A study of Daphnia magna with 16 samples.

How the data were processed

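Gene expression was measured in whole *Daphnia magna* on 2-colour Agilent arrays of 3802 probes with 4 spots each (15208 spots), laid out on 2 slides. Per the labels, Cy5 holds the sample and Cy3 a reference pooled from controls, always in this dye orientation. Animals were exposed for 21 days, and the 15 arrays used here form 5 groups of 3: medium, methanol, and HCCPD at the low, middle and high dose. The labels give methanol no role, and it is treated here as the carrier control.

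Per the file headers, the deposited scanner files hold intensity values on a linear scale, as the mean pixel intensity of each spot and the median of its local background, made by Agilent Feature Extraction 10.1.1.1. Per the file headers, they also hold a log10 ratio of red over green, after background subtraction, spatial detrending and dye normalization by Feature Extraction. The authors' deposited table gives log2 fold change, p-value and FDR for 10 comparisons; per the submitters' processing notes limma was among the tools, with no version. Its log base was settled from the values, whose slope against log2 of the scanner ratios is near 1.

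Intensities were background-corrected by normexp with offset 50 and normalized within arrays by loess, with control spots and non-uniform spots at weight 0, and the 4 spots of a probe were averaged. Probes well above background in Cy5 on at least 3 of the 15 arrays were tested, which left 2880, of which 2379 were well above background on all 15. The arrays carried 459 positive and 77 negative control spots. One linear model with 5 group means (10 residual degrees of freedom, prior 1.98) was fitted with limma 3.58.1 in R 4.3.3, and probes were called at a Benjamini-Hochberg adjusted p under 0.05 with no fold threshold. The median standard error of a log2 fold change between groups of 3 was 0.146, and the number of arrays limits this precision. Tables were handled with data.table (version 1.17.8), Python 3.11.15 and pandas 2.3.3, and figures drawn with matplotlib 3.10.9.

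Gene names came from the authors' deposited table alone, which lists 2611 probes, from the best protein hit with an E-value of at most 1e-05 or a *D. magna* nucleotide hit; 595 probes had such a protein hit and 373 an informative name. The authors' deposited table holds no probe with a log2 fold change of 1 or more in either direction in its 10 comparisons. Named genes and list members are therefore selected by size of change: genes with larger differences have no name here, and the list tests cover only the rest. The reference table of gene symbols has no link to the probes and was not used. In all, 30 gene lists were made by matching names, holding 144 probes, and the 13 lists with at least 5 tested probes were tested in 6 comparisons (78 tests) by camera with a preset correlation of 0.01, adjusted over all 78. The same lists were tested by camera with an estimated correlation and by fry. Lists can share probes, and repeated probes of one gene count as separate members. The E-value limit and the cleaning of names were chosen after seeing the columns of that table and before any fold change. Single genes are named by a rule: up to 12 highest and 12 lowest of the called probes, filled to 6 per direction with the smallest p where fewer are called, and 2 to 4 members of each list that passed. Adjustment over a list alone used the limma p-values of its members. It was done separately for each of the 78 list tests with no adjustment for their number, so some lists can hold a pass by chance alone.

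The comparisons, the groups, the tests and most alternatives were chosen before the data were examined. The alternatives were slide as a block, replicate number as a block, other control groups, other background and dye normalizations, the deposited LogRatio, the Cy5 channel alone, array weights, an adjusted p under 0.1, the QC self-replicate added to the low dose, and leaving out each array in turn. Those chosen after seeing the data were leaving HCCPD middle replicate 2 out of comparisons it is not part of and, for the gene lists, members added by GO terms, leaving out each array, the normalizations and medium as the control. The correlation expected from shared controls came from 100 simulations with seed 1.

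The path was tested on simulated data in which 200 of 2880 probes changed, 100 by a log2 of 0.5 and 100 by a log2 of 1. At a log2 change of 0.5 and 1, the share called was 55% and 80% for methanol against medium, 51% and 81% for the low, 48% and 84% for the middle and 46% and 72% for the high dose against methanol, 48% and 81% for the high against the low dose, and 78% and 92% for all HCCPD against all controls. False calls numbered 9, 3, 6, 4, 6 and 10, with 0 in the wrong direction. These shares hold for 200 changed probes and noise that is independent between probes and equal in all groups, so they need not carry over to the arrays. In the data, 113, 79 and 34 probes differed at least 2-fold from methanol at the low, middle and high dose, and 0 were called. In the high-dose Cy5 intensities, 200 probes were then shifted by log2 1, 100 raised and 100 lowered. The median recovered was 0.85 and 100% went in the right direction. Where the ribosomal proteins were moved by 0.3, camera gave an adjusted p of 8.47e-22 with the preset and 9.85e-06 with an estimated correlation, and 0 other lists passed. The simulated noise was independent between probes, whereas the estimated correlation of this list in the data was 0.496. The simulation therefore cannot tell how either setting behaves with correlated members.

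The QC self-replicate at the low dose was left out of the groups, as it is a repeat and no further replicate. Probes that are not well above background were left out as too dim to compare.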

Results

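Whole animals of *Daphnia magna*, a freshwater crustacean that reproduces mainly by parthenogenesis and is widely used in ecotoxicology, were exposed for 21 days to hexachlorocyclopentadiene (HCCPD), a chlorinated intermediate in the manufacture of pesticides and flame retardants. The low, middle and high doses were 0.138, 1.38 and 13.8 µg/L. The controls were kept in culture medium alone or with methanol, which is taken here as the carrier control. Each of the 5 groups had 3 arrays, and every array compared one sample (Cy5) with a reference pooled from controls (Cy3). The labels call the samples biological replicates without saying whether they came from separate animals or cultures. The limma p-values below therefore weigh differences against the spread between these samples, whatever its source. Camera p-values set list members against the other probes and depend on the correlation taken between members. Of 3802 probes on the array, 2880 were bright enough to test, and 330 of these carried a gene name. All log2 fold changes are given with their standard error from limma, and all group means are log2 ratios of sample to reference with the SD over 3 arrays.

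Between 67.3% and 77.1% of spots were well above background in the Cy5 channel on 14 of the 15 arrays. On HCCPD middle replicate 2 the share was 95.1%, with a median Cy5 intensity of 432 against 159 to 193 on the other 14 arrays. No Cy5 spot was saturated (0%). Across probes, which are not independent replicates, log ratios of arrays correlated by 0.470 on average within groups and by 0.426 between groups. The correlation was 0.738 within the low dose and 0.320 within methanol. The first principal component of the 14 arrays without HCCPD middle replicate 2 held 41.2% of the variance, and the methanol replicates lay far apart on it, at 11.8, −28.8 and −12.5. All 20 ribosomal protein probes loaded positively on this axis, while 11 of 12 oxidative phosphorylation probes, 7 of 7 glycolysis and citrate cycle probes, 7 of 7 transport ATPase probes and 7 of 8 digestive peptidase probes loaded negatively.

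**Figure D1:**
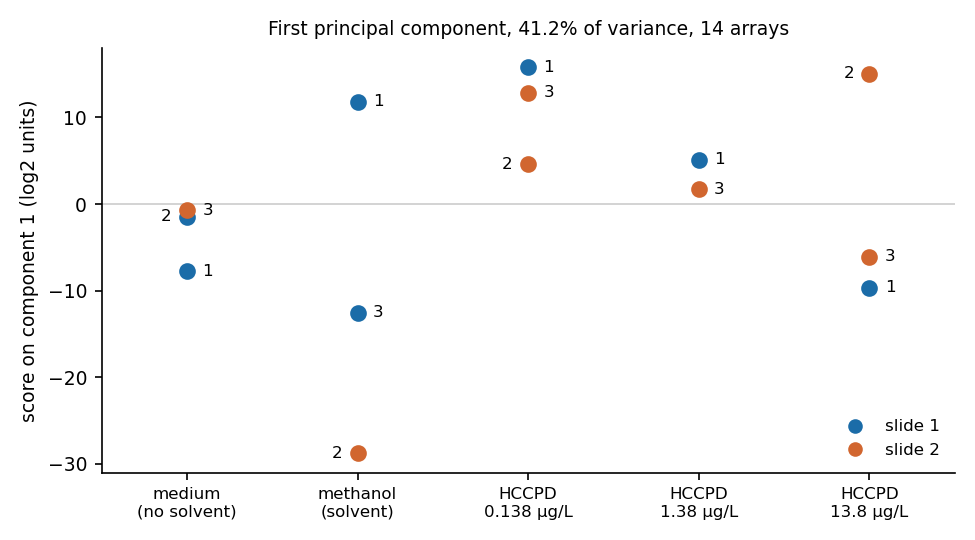
Score of each of 14 arrays on the first principal component of the log2 ratios (vertical axis, log2 units), by group, coloured by slide and marked with the replicate number. The methanol arrays spread from −28.8 to 11.8, wider than any other group.

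Methanol was compared with medium to see what the carrier alone did. Here and below, a list called higher or lower as a group passed only in camera with a preset correlation of 0.01, and 0 lists passed with an estimated correlation. Digestive glycosidases, which break down polysaccharides in food, were higher in methanol as a group (7 of 7 probes higher, median log2 fold change 0.19, adjusted p = 0.582 with an estimated correlation). Matched by name, this list also held Glucosidase, beta, acid (0.09 ± 0.14), which need not be digestive. Cytochrome P450 enzymes, which oxidise foreign compounds and many lipids, were also higher as a group (7 of 8 probes, median 0.11, adjusted p = 0.577 with an estimated correlation), as were digestive peptidases (5 of 8 probes, median 0.13, adjusted p = 0.635 with an estimated correlation). Ribosomal proteins, the building blocks of the ribosome, were lower as a group (19 of 20 probes, median −0.09, adjusted p = 0.635 with an estimated correlation). Among the single genes, cytochrome P450 3A had a log2 fold change of 0.34 ± 0.11, with means of 0.37 ± 0.09 in methanol and 0.03 ± 0.05 in medium (SD, n = 3). Chymotrypsin BI stood at 0.29 ± 0.13, the digestive trypsin at 0.35 ± 0.18 and the starch-cleaving alpha-amylase at 0.39 ± 0.20. On the other side, Gaba(A) receptor associated protein, which belongs to a family that builds autophagosomes, stood at −0.18 ± 0.07, Ribosomal Protein L18A at −0.18 ± 0.07 and the cysteine-rich secretory protein CRISP-ENH2 at −0.36 ± 0.14. None of these genes passed.

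limma called 0 of 2880 probes between methanol and medium, with 56 at an unadjusted p under 0.05 where chance alone gives 144, and 49 with slide as a block. That count was 118 without methanol replicate 1, 31 without methanol replicate 2, 38 without medium replicate 2 and 23 without medium replicate 3, and with array weights it was 222, above the number given by chance. In camera with a preset correlation, adjusted p = 0.000878 for the glycosidases, 0.00698 for cytochrome P450, 0.0309 for the peptidases and 0.000218 for the ribosomal proteins. With slide as a block the values were 0.000722, 0.00715, 0.0371 and 0.000142. Over the 78 list tests of all comparisons, 17 passed in camera with a preset correlation (24 at an unadjusted p under 0.05), 0 in camera with an estimated correlation (6), 0 in fry (9, smallest adjusted p = 0.174) and 0 in fry for changes in either direction (3). The estimated correlation of the lists that passed ran from 0.0683 (glycolysis and citrate cycle) to 0.496 (ribosomal proteins), above the preset of 0.01. The preset therefore treats the members as closer to independent than was estimated. The list medians were 0.22 on slide 1 and 0.11 on slide 2 for the glycosidases, 0.15 and 0.04 for cytochrome P450, 0.10 and 0.26 for the peptidases, and 0.02 and −0.34 for the ribosomal proteins, whose sign therefore differed between slides. Slide 2 held 1 methanol array, replicate 2, which scored −28.8 on the main axis of the arrays. All slide 2 differences from methanol, here and below, therefore rest on that array, and slide cannot be told apart from it. In all 4 lists, 0 members passed when adjusted over the list alone, and 0 over all probes. Without methanol replicate 1 the glycosidases, cytochrome P450 and the peptidases no longer passed in camera (adjusted p = 0.299, 0.227 and 0.452), and without methanol replicate 2 the ribosomal proteins did not (0.804); the ranges over all alternatives were 3.31e-07 to 0.582, 0.00296 to 0.577, 0.00649 to 0.635 and 1.56e-07 to 0.804. Without medium replicate 3 the glycosidases (0.119) and the peptidases (0.386) did not pass, without HCCPD middle replicate 2 the peptidases did not (0.0894), and from the Cy5 channel alone the P450 (0.144), peptidase (0.0537) and ribosomal (0.186) lists did not. The peptidases also failed in camera from the deposited LogRatio (0.0526) and with members added by GO terms (0.0716).

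The low dose was compared with methanol to ask what HCCPD did at 0.138 µg/L. Digestive peptidases, mostly gut enzymes that cleave dietary protein, were lower as a group at this dose (7 of 8 probes, median log2 fold change −0.35, adjusted p = 0.469 with an estimated correlation). The 10 probes matched to this list by name, of which 8 were tested, include a leukocyte elastase inhibitor, which is no digestive enzyme. The fold change was −0.59 ± 0.18 for trypsin (probe EA_Dma_AF_100391), with means of −0.46 ± 0.27 at the low dose and 0.13 ± 0.14 in methanol (SD, n = 3), −0.42 ± 0.13 for chymotrypsin BI and −0.42 ± 0.14 for carboxypeptidase B. Digestive glycosidases were lower as a group (6 of 7 probes, median −0.25, adjusted p = 0.635 with an estimated correlation), led by alpha-amylase at −0.67 ± 0.20 and the mannan-cleaving Mannan endo-1,4-beta-mannosidase precursor at −0.58 ± 0.20. Ribosomal proteins were higher as a group in 20 of 20 probes (median 0.16, adjusted p = 0.635 with an estimated correlation), among them ribosomal protein S11 at 0.30 ± 0.12 and ribosomal protein S27 at 0.22 ± 0.08.

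Transport ATPases were lower as a group at the low dose in 7 of 7 probes (median −0.28, adjusted p = 0.469 with an estimated correlation). They included subunits of the sodium pump that sets the cell's ion gradients, at −0.75 ± 0.36 for the alpha subunit of the Na/K ATPase and −0.50 ± 0.21 for its beta subunit, and of the vacuolar proton pump, at −0.28 ± 0.11 for Vha68-2. The list also held AFG3-like 2, which is a mitochondrial protease and no transporter, at −0.15 ± 0.17. The oxidative phosphorylation list was lower too (10 of 12 probes, median −0.14, adjusted p = 0.635 with an estimated correlation), a call that also ended with slide as a block. Of its 3 members with the smallest p, V1 subunit A at −0.33 ± 0.13 and Vha68-2 belong to the vacuolar proton pump, and only the NADH-ubiquinone oxidoreductase 42 kDa subunit, at −0.28 ± 0.12, is part of the respiratory chain. The Vha68-2 and V1 subunit A probes are also members of the transport ATPase list, so the calls of these lists are not independent. Cytochrome P450 3A had the smallest p of any named gene here (−0.43 ± 0.11) and legumaturain stood at −0.70 ± 0.20. In methanol both stood above medium, by 0.34 ± 0.11 and 0.33 ± 0.20, so both falls are smaller when taken from medium. Towards higher values lay transthyretin (0.33 ± 0.10), Sec61 Gamma Subunit, part of the channel through which proteins enter the endoplasmic reticulum (0.30 ± 0.12), and the vesicle coat protein epsilon subunit of coatomer (0.26 ± 0.11). No single gene passed over all probes.

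limma called 0 probes between the low dose and methanol, with 228 at an unadjusted p under 0.05 (144 by chance), of which 129 were lower, and 201 with slide as a block. That count was 356 without methanol replicate 1, 79 without methanol replicate 2, 102 without HCCPD low replicate 1, 129 without HCCPD low replicate 3, 124 against medium and 467 with array weights. The smallest adjusted p in limma was 0.222, for the unnamed probe EA_Dma_UN_107184, at −0.56 ± 0.10. In camera with a preset correlation, adjusted p = 0.000218 for the peptidases, 0.0110 for the glycosidases, 5.48e-06 for the ribosomal proteins, 0.00410 for the transport ATPases and 0.0309 for oxidative phosphorylation. In the same order, the values with slide as a block were 0.000142, 0.0236, 7.60e-07, 0.00298 and 0.0501. The ribosomal proteins lie on one side of the main axis of the arrays and most peptidases, transport ATPases and oxidative phosphorylation probes on the other. The 3 low-dose arrays (up to 15.8) and methanol replicate 2 (−28.8) lie on opposite sides of 0 on that axis, and the 5 lists passed in camera without that replicate. On slides 1 and 2 the list medians were −0.51 and −0.30 for the peptidases, −0.47 and 0.05 for the glycosidases, 0.17 and 0.30 for the ribosomal proteins, −0.25 and −0.34 for the transport ATPases, and −0.21 and −0.14 for oxidative phosphorylation. Where 0 members passed over all probes, 4 of the peptidases (chymotrypsin BI, carboxypeptidase B and the trypsin probes EA_Dma_AF_100391 and EA_Dma_AF_102233), 2 of the glycosidases (alpha-amylase and the mannosidase) and cytochrome P450 3A passed when adjusted over the list alone (smallest adjusted p = 0.0251, 0.0387 and 0.0193 in limma). Methanol itself stood above medium in 5 of 8 peptidase probes, 7 of 7 glycosidase probes and cytochrome P450 3A (0.34 ± 0.11). For such probes a fall from methanol is smaller when taken from medium. The glycosidases no longer passed in camera against medium (adjusted p = 0.709), against both controls (0.0888), without HCCPD low replicate 1 (0.0519) or without methanol replicate 1 (0.299), with a range of 6.81e-06 to 0.709 over all alternatives. Oxidative phosphorylation also failed without HCCPD low replicate 1 (0.144), without methanol replicate 1 (0.135), from the Cy5 channel alone (0.186), from the deposited LogRatio (0.0711) and with members added by GO terms (0.125), with a range of 0.0116 to 0.635.

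The middle dose was compared with methanol to ask what HCCPD did at 1.38 µg/L. Ribosomal proteins were higher as a group (17 of 20 probes, median log2 fold change 0.17, adjusted p = 0.651 with an estimated correlation), among them ribosomal protein L34 at 0.37 ± 0.14, ribosomal protein L23A at 0.34 ± 0.15 and ribosomal protein S11 at 0.28 ± 0.12. The yolk precursor vitellogenin fused with superoxide dismutase, an enzyme that removes superoxide, had a fold change of 0.40 ± 0.13, with means of −0.21 ± 0.17 at the middle dose and −0.60 ± 0.14 in methanol (SD, n = 3). Cytochrome P450 2D20 stood at 0.76 ± 0.28 and the oxygen carrier hemoglobin (Dhb1) at 0.16 ± 0.06. The smallest p of a named gene belonged to the Brain-specific membrane-anchored protein precursor, at −0.44 ± 0.09. Also towards lower values lay lupus la ribonucleoprotein, which binds new transcripts of RNA polymerase III (−0.47 ± 0.13), RNA polymerase III subunit RPC2 itself (−0.38 ± 0.12), the nuclear import receptor Importin alpha-2 subunit (−0.33 ± 0.10) and legumain-like protease precursor (−0.31 ± 0.10). None of these genes passed.

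limma called 0 probes between the middle dose and methanol, with 434 at an unadjusted p under 0.05 (144 by chance), of which 283 were lower, 392 with slide as a block, 262 without methanol replicate 2 and 207 with only the compared groups in the fit. The smallest adjusted p was 0.0750, for the unnamed probe EA_Dma_AM_102402, at 1.01 ± 0.15. For the ribosomal proteins, adjusted p = 0.000579 in camera with a preset correlation and 0.000414 with slide as a block. The list's medians were 0.04 on slide 1 and 0.39 on slide 2, and 0 members passed over all probes or adjusted over the list alone. The list no longer passed in camera against medium (adjusted p = 0.189) or without methanol replicate 2 (0.0794), with a range of 2.00e-05 to 0.651. Without HCCPD middle replicate 1, limma called 25 probes (3 higher, 22 lower), including RPC2 at −0.51, and without replicate 2, whose array stood apart, or replicate 3 it called 3 probes each.

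The high dose was compared with methanol to ask what HCCPD did at 13.8 µg/L. Ribosomal proteins were higher as a group (17 of 20 probes, median log2 fold change 0.11, adjusted p = 0.658 with an estimated correlation), among them ribosomal protein L5 at 0.24 ± 0.12 and ribosomal protein L23A at 0.25 ± 0.15. Vitellogenin fused with superoxide dismutase (probe EA_Dma_AF_101703) had the smallest p of all probes, at 0.60 ± 0.13, with means of −0.01 ± 0.16 at the high dose and −0.60 ± 0.14 in methanol (SD, n = 3). Peroxinectin, an adhesion protein of crustacean blood cells, stood at 0.89 ± 0.35 and dihydropyrimidine dehydrogenase, which breaks down pyrimidines, at 0.19 ± 0.08. Towards lower values lay a digestive trypsin (probe EA_Dma_AF_102233, −0.39 ± 0.13), the endoribonuclease endoU protein (−0.74 ± 0.32), lupus la ribonucleoprotein (−0.39 ± 0.13), the Brain-specific membrane-anchored protein precursor (−0.31 ± 0.09) and ADP-ribosylation-like factor 6 interacting protein 5 (−0.23 ± 0.07). None of these genes passed over all probes. The ubiquitin ligase scaffold Cullin homolog 1 (CUL-1) was not well above background on any methanol array and is given no fold.

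limma called 0 probes between the high dose and methanol, with 166 at an unadjusted p under 0.05 (144 by chance), of which 143 were lower, and 165 with slide as a block. That count was 37 without HCCPD high replicate 2, 252 without HCCPD middle replicate 2, 107 from the Cy5 channel alone and 282 with array weights. For the vitellogenin probe, adjusted p = 0.661 in limma over all probes and 0.00464 when adjusted over the list alone, where it was the 1 of 6 members to pass; its fold change was 0.61 on slide 1 and 0.50 on slide 2. For the ribosomal proteins, adjusted p = 0.000878 in camera with a preset correlation and 0.000327 with slide as a block. Their medians were 0.04 on slide 1 and 0.30 on slide 2, and 0 members passed when adjusted over the list alone. The ribosomal list no longer passed in camera against medium (adjusted p = 0.823), against both controls (0.0665), from the deposited LogRatio (0.0747) or without methanol replicate 2 (0.407), with a range of 2.06e-05 to 0.823. CUB and Sushi multiple domains 3, at 0.32 ± 0.17 here, stood at −0.17 on slide 1 and 0.73 on slide 2.

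The high dose was compared with the low dose to ask what differed over the dose range, with no control array shared. Vitellogenin and yolk or egg proteins, which provision the eggs, were higher as a group at the high dose (5 of 6 probes, median log2 fold change 0.24, adjusted p = 0.469 with an estimated correlation). Vitellogenin fused with superoxide dismutase was higher by 0.90 ± 0.13 (probe EA_Dma_AF_101703) and passed only when adjusted over the list alone. Its means were −0.91 ± 0.13 at the low and −0.01 ± 0.16 at the high dose (SD, n = 3), and all 3 high-dose arrays lay above all 3 low-dose arrays. A further probe of the same best hit, EA_Dma_AM_102271, was higher by 0.52 ± 0.18 and passed by the same criterion only, and EA_Dma_AF_101415 stood at 0.36 ± 0.18. The other members stood closer to 0, with vitellogenin C1 at −0.08 ± 0.24, the receptor that takes yolk into the egg at 0.12 ± 0.11 and vitelline membrane outer layer protein I-like protein at 0.05 ± 0.20. In medium and methanol, the means of probe EA_Dma_AF_101703 were −0.55 ± 0.21 and −0.60 ± 0.14.

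**Figure D2:**
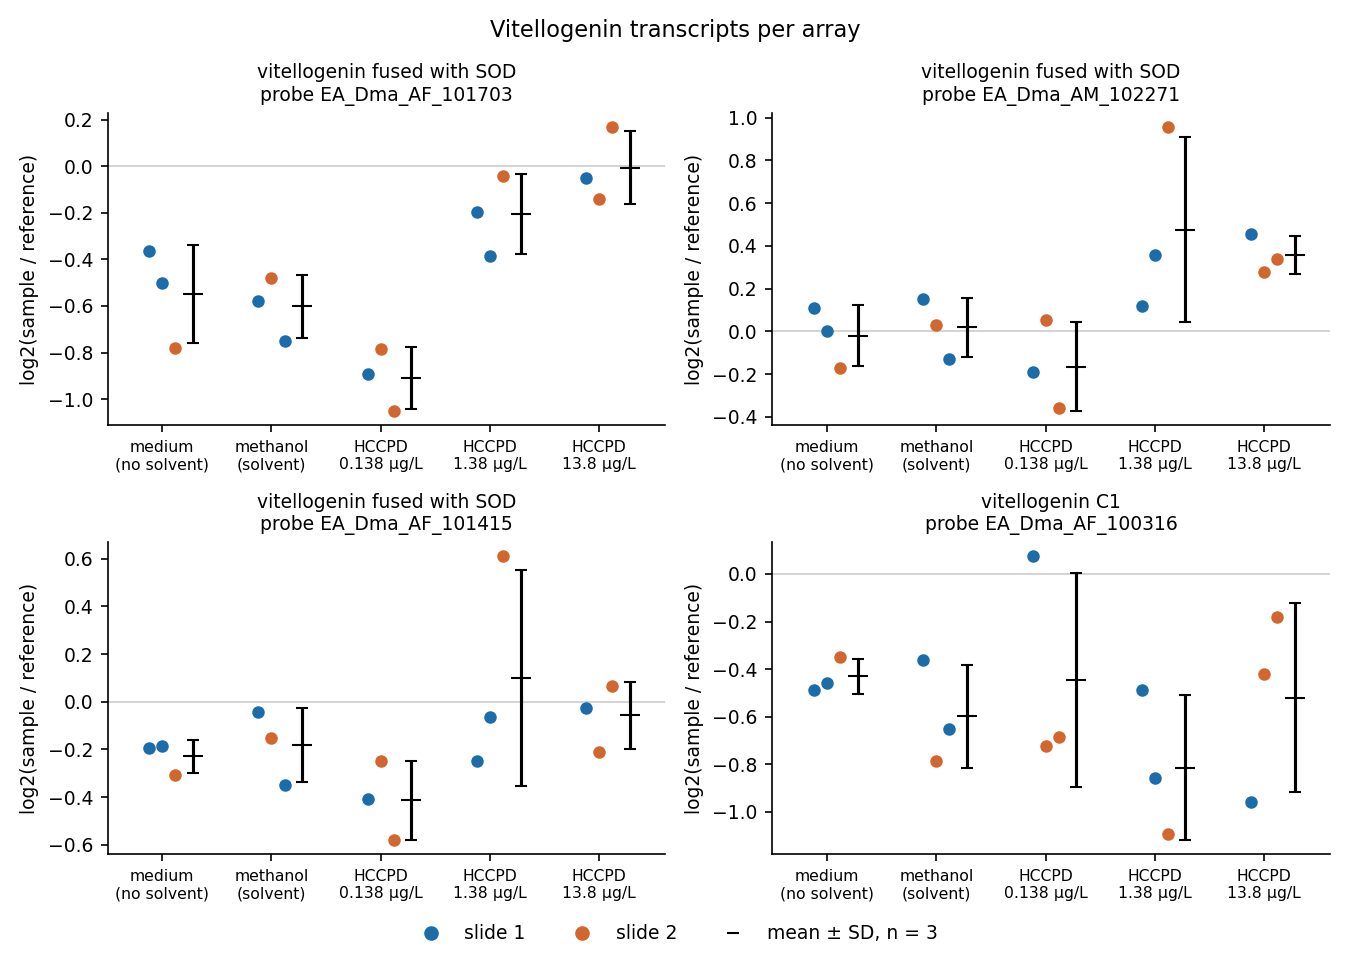
Log2 ratio of sample to reference (vertical axis) of 4 vitellogenin probes in each of the 5 groups; points are arrays coloured by slide, and bars are the mean ± SD of 3 arrays. For probe EA_Dma_AF_101703, the 3 high-dose arrays lie above the 3 low-dose arrays on both slides, while vitellogenin C1 shows no such gap.

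Enzymes of glycolysis and the citrate cycle were higher as a group at the high dose than at the low dose (7 of 7 probes, median 0.17, adjusted p = 0.469 with an estimated correlation), among them NADPH-specific isocitrate dehydrogenase at 0.33 ± 0.15, fructose 1,6-bisphosphate aldolase at 0.17 ± 0.09 and Phosphoglycerate kinase at 0.14 ± 0.06. Transport ATPases were higher as a group (6 of 7 probes, median 0.25, adjusted p = 0.561 with an estimated correlation). Their members with the smallest p were AFG3-like 2, a mitochondrial protease (0.42 ± 0.17), the proton pump subunit Vha68-2 (0.24 ± 0.11) and the beta subunit of the sodium pump (0.46 ± 0.21). Digestive peptidases were higher as a group (7 of 8 probes, median 0.21, adjusted p = 0.635 with an estimated correlation), with chymotrypsin BI at 0.30 ± 0.13 and trypsin at 0.33 ± 0.18. Outside these lists, Glutaryl-Coenzyme A dehydrogenase, which breaks down lysine and tryptophan, stood at 0.70 ± 0.18, a sulfate transporter at 0.66 ± 0.21 and 2-phospho-D-glycerate hydrolase, the glycolytic enolase, at 0.28 ± 0.10. Towards lower values at the high dose lay transthyretin (−0.38 ± 0.10), Myol protein (−0.47 ± 0.13), lupus la ribonucleoprotein (−0.34 ± 0.13) and ribosomal protein L29e (−0.30 ± 0.11).

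limma called 0 probes between the high and the low dose, with 275 at an unadjusted p under 0.05 (144 by chance), of which 188 were lower, and 256 with slide as a block. That count was 169 without HCCPD low replicate 2, 430 without HCCPD middle replicate 2 and 448 with array weights. The smallest adjusted p of all probes in limma was 0.0572, for the vitellogenin probe, whose fold change was 0.85 on slide 1, 0.93 on slide 2 and 0.90 with slide as a block (adjusted p = 0.132). Over the alternatives the adjusted p ran from 0.0505 to 0.297, apart from 0.0224 in limma when the QC self-replicate, which is a repeat and no further sample, was added to the low dose. Over its list alone the probe had an adjusted p of 0.000119, and 2 of 6 members passed when adjusted over the list alone, against 0 over all probes. In the authors' deposited table, this probe is the 1 listed probe with an FDR under 0.05 in 10 comparisons, with a log2 fold change of 0.97 and FDR of 0.0450 between these doses. The authors' deposited table lists 2611 of the 3802 probes and none at a 2-fold difference or more, so probes it leaves out may have passed as well. In camera with a preset correlation, adjusted p = 0.00526 for the yolk list, 0.0111 for glycolysis and the citrate cycle, 0.0110 for the transport ATPases and 0.0467 for the peptidases. In the same order, the values with slide as a block were 0.00505, 0.0125, 0.0124 and 0.0502, where the peptidase call ended. On slides 1 and 2 the medians were 0.36 and 0.37 for the yolk list, 0.26 and 0.09 for glycolysis and the citrate cycle, 0.18 and 0.28 for the transport ATPases, and 0.35 and 0.13 for the peptidases. Apart from the yolk list, 0 members of these lists passed when adjusted over the list alone. Without HCCPD high replicate 3, none of the 4 lists passed in camera (adjusted p = 0.0600, 0.115, 0.117 and 0.358), with ranges over all alternatives of 0.00135 to 0.469, 0.00267 to 0.469, 0.000947 to 0.561 and 0.00350 to 0.635. The peptidases also failed without HCCPD low replicate 1 (0.298) or replicate 3 (0.0773), without HCCPD middle replicate 1, 2 or 3 (0.0758, 0.115 and 0.0619), without methanol replicate 1 or 2 (0.0508 and 0.0514), with medium or both controls as the control (0.0529), without background subtraction (0.0533), from the deposited LogRatio (0.0711) and from the Cy5 channel alone (0.209), glycolysis and the citrate cycle from the Cy5 channel alone (0.0922), and the transport ATPases with members added by GO terms (0.0891).

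The 9 HCCPD arrays were compared with the 6 control arrays, as the mean of the 3 dose groups against the mean of both control groups. Digestive peptidases were lower as a group over all doses (8 of 8 probes, median log2 fold change −0.19, adjusted p = 0.635 with an estimated correlation). A serine protease (probe EA_Dma_AF_101238) was lower by 0.28 ± 0.07 and passed only when adjusted over the list alone. Its means were 0.01 ± 0.13 (SD, n = 9) under HCCPD and 0.29 ± 0.15 (SD, n = 6) in the controls, and carboxypeptidase B stood at −0.25 ± 0.09. Ribosomal proteins were higher as a group (16 of 20 probes, median 0.09, adjusted p = 0.635 with an estimated correlation), with ribosomal protein S11 at 0.18 ± 0.08. Fatty acid binding protein 15, which carries fatty acids within cells, stood at −0.47 ± 0.15, the Brain-specific membrane-anchored protein precursor at −0.32 ± 0.06, V1 subunit A of the vacuolar proton pump at −0.26 ± 0.08 and legumain-like protease precursor at −0.20 ± 0.06. Towards higher values lay peroxinectin (0.59 ± 0.23), vitellogenin fused with superoxide dismutase (0.20 ± 0.09) and hemoglobin (Dhb1) (0.10 ± 0.04). None of these genes passed over all probes.

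limma called 0 probes between HCCPD and the controls, with 337 at an unadjusted p under 0.05 (144 by chance), of which 268 were lower, and 284 with slide as a block. That count was 173 without medium replicate 1, 214 without HCCPD low replicate 1, 187 without HCCPD high replicate 2, 543 without HCCPD middle replicate 2 and 570 with array weights. In camera with a preset correlation, adjusted p = 0.0431 for the peptidases and 0.000218 for the ribosomal proteins. In the same order, the values with slide as a block were 0.0525 and 0.000142, where the peptidase call ended. The medians on slides 1 and 2 were −0.26 and 0.03 for the peptidases and 0.08 and 0.15 for the ribosomal proteins. Of the peptidases, 1 passed when adjusted over the list alone (the serine protease, adjusted p = 0.0222 in limma), and of the ribosomal proteins 0 did, against 0 over all probes. The peptidases no longer passed without methanol replicate 1 (0.195), medium replicate 2 (0.123), HCCPD low replicate 1 or 3 (0.0671 and 0.0649), HCCPD middle replicate 1, 2 or 3 (0.0822, 0.101 and 0.116) or HCCPD high replicate 1 (0.0941), nor from the deposited LogRatio (0.113), from the Cy5 channel alone (0.0799) or with members added by GO terms (0.125), with a range of 0.00803 to 0.635, whereas the ribosomal proteins passed in every camera alternative other than the estimated correlation (1.91e-05 to 0.635) and not in fry (adjusted p = 0.493, and 0.898 for changes in either direction).

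**Figure D3:**
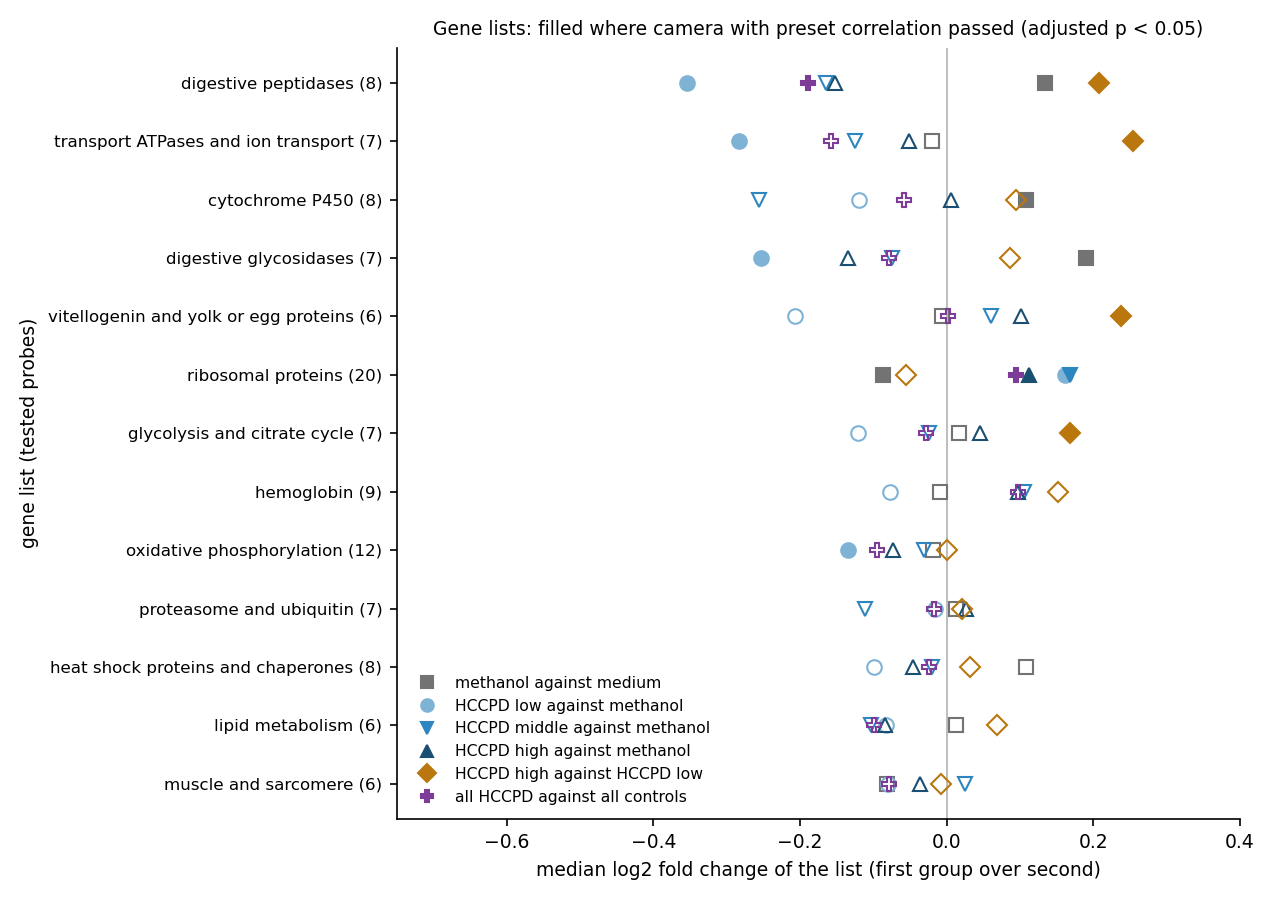
Median log2 fold change (horizontal axis) of 13 gene lists in 6 comparisons, with filled marks where camera with a preset correlation passed, which it did in 17 of 78 tests. With an estimated correlation 0 of the 78 tests passed. Digestive peptidases lie at −0.35 and transport ATPases at −0.28 in the low dose against methanol, and ribosomal proteins at 0.16 in the same comparison.

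The responses to the 3 doses were set side by side over the 2880 probes, which are not independent replicates. Fold changes from methanol correlated by 0.591 between the low and the middle dose, 0.653 between the low and the high dose and 0.610 between the middle and the high dose, where unchanged groups simulated against shared controls gave 0.503, 0.502 and 0.503. The covariances were 0.102, 0.0794 and 0.0720 against simulated values of at most 0.0402. The share of probes with the same sign was below the simulated share for the low and the middle dose (58.3% against 66.8%) and for the low and the high dose (61.5% against 66.7%), and above it for the middle and the high dose (69.6% against 66.8%). limma called 0 probes at any dose, so 0 were called at a pair of doses and independent lists also give 0. At an unadjusted p under 0.05, 43 probes were higher and 25 lower at both the low and the middle dose, where independent lists give 5.19 and 12.7. For the low and the high dose these counts were 4 and 11 (0.791 and 6.41), and for the middle and the high dose 11 and 36 (1.21 and 14.1). Independent lists leave out the shared methanol arrays, and the simulation gave every group the same spread per probe. Methanol had the lowest mean correlation within a group (0.320), and its spread enters the fold changes of all 3 doses. An excess over either value therefore cannot be told apart from an effect of the shared controls. The 3 methanol arrays could not be split into parts of at least 2 arrays to separate these. With one dose set against methanol and the other against medium, so that no array was shared, the correlations ran from −0.0334 to 0.425. Between slides, the fold changes of one comparison correlated across probes by 0.0194 for methanol against medium, 0.641 for the low, 0.325 for the middle and −0.358 for the high dose against methanol, 0.436 for the high against the low dose and 0.140 for all HCCPD against all controls. For methanol against medium and the 3 doses against methanol, slide 2 gave methanol replicate 2 alone. These correlations therefore cannot tell slide from that array.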

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

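At an adjusted p under 0.05, limma called 0 probes in 19 of 19 alternatives for methanol against medium, 20 of 21 for the low, 14 of 20 for the middle and 21 of 21 for the high dose against methanol, 18 of 19 for the high against the low dose and 25 of 27 for all HCCPD against all controls. These counts leave out the looser threshold of 0.1, at which 1 probe was called in the middle dose and 1 between the high and the low dose. In the middle dose 1 probe was called from the deposited LogRatio, 1 with the QC self-replicate added and 1 against both controls together, and leaving out single arrays gave 0 to 25, the most without HCCPD middle replicate 1 (3 higher, 22 lower). Array weights gave 1 call for the low dose and 1 for all HCCPD against all controls, where leaving out single arrays gave 0 to 1 (1 without HCCPD middle replicate 2). Between the high and the low dose 1 probe was called with the QC self-replicate, a repeat of a low-dose sample, added to the low dose: the vitellogenin fused with superoxide dismutase at 0.87 (adjusted p = 0.0224 in limma; 0.0505 to 0.297 over the other alternatives). Of 78 gene list tests, 17 passed in camera. With an estimated correlation 0 passed (6 at an unadjusted p under 0.05), and from the Cy5 channel alone 11 did, 10 of them among the 17. Leaving out single arrays gave 10 passes (without methanol replicate 1, all 10 among the 17) to 20 (without HCCPD high replicate 2, all 17 included). Slide as a block gave 14 passes (14 among the 17), medium as the control 14 (13), GO terms 15 of 120 tests (13) and the deposited LogRatio 12 (12), and no list that passed turned direction. Quantile normalization of the mean intensities leaves log ratios unchanged, so its result says nothing. The replicate numbers do not pair the arrays: 8 of 30 same-number pairs correlated above 0.1, with a mean of −0.0721 against 0.0385 for other numbers, and with replicate number as a block limma called 0 probes in each comparison and 15 list tests passed, all 15 among the 17; the digestive peptidases between the high and the low dose and over all doses did not (adjusted p = 0.0581 in camera for both). Of 118 named values, chosen for a small p in the same arrays so that stable signs say little, 114 never changed sign. The others were ribosomal protein S27 (EA_Dma_AF_100392) in methanol against medium, at 0.064 from the Cy5 channel alone; hemoglobin (Dhb1) (EA_Dma_AM_102309) at the middle dose, at −0.040 from the Cy5 channel alone; CUB and Sushi multiple domains 3 (EA_Dma_AF_101232) at the high dose, at −0.060 against medium; and vitelline membrane outer layer protein I-like protein (EA_Dma_AF_101255) between the high and the low dose, at −0.040 with array weights and −0.083 (without HCCPD high replicate 3) to 0.25 (without replicate 1) over left-out arrays.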

Other observations

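Hemoglobins, the oxygen carriers of *Daphnia* blood, did not pass as a group in any comparison; their smallest adjusted p in camera was 0.135, between the high and the low dose (6 of 9 probes higher, median log2 fold change 0.15). Single hemoglobin probes in that comparison stood at 0.44 ± 0.18 (EA_Dma_AF_101424) and 0.51 ± 0.21 (dhb3). Heat shock proteins and chaperones, which help proteins fold, had a smallest adjusted p of 0.301, with Hsp90 at −0.37 ± 0.24 in the high dose against methanol and Hsp70 at −0.45 ± 0.31 in the low. The smallest adjusted p was 0.325 for lipid metabolism, 0.504 for proteasome and ubiquitin and 0.668 for muscle and sarcomere, where tropomyosin, which lies along actin filaments, stood at −0.33 ± 0.17 in the low dose. Fatty acid binding protein 15 stood at −0.49 ± 0.23, −0.60 ± 0.23 and −0.50 ± 0.23 at the 3 doses. Cytochrome P450 in all HCCPD against all controls had a positive direction in camera and a mean of 0.01 but a median of −0.06.

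Of the 17 lists too short to test, glutathione S-transferases (3 probes), which conjugate foreign compounds with glutathione, had Glutathione S transferase 1 at −0.40 ± 0.17 in the low and −0.36 ± 0.17 in the high dose against methanol. The ecdysteroid list held 1 probe, the retinoid X receptor, the partner of the ecdysone receptor, at −0.27 ± 0.12 in the low dose, and the lectin list 1 C-type lectin, a sugar-binding protein, at −0.43 ± 0.19. The antioxidant list (4 probes, 3 of them the vitellogenin fused with superoxide dismutase) had peroxiredoxin V at −0.12 ± 0.09 in the high dose, the metal list (2) the iron store ferritin at 0.39 ± 0.32 in the middle dose, histones (2) histone H3 at 0.18 ± 0.22 in the low dose and DNA repair and apoptosis (3) p53 at −0.18 ± 0.16 in the middle dose. None of these passed in limma. Other phase II enzymes and neuronal signalling had 4 tested probes each, chitin metabolism, vision (a transthyretin, no photoreceptor gene) and extracellular matrix 1 each, and cuticle, juvenile hormone, cell cycle, algal food and sex determination 0 each. Every probe with at least a 2-fold difference lacks a name (50, 113, 79, 34, 43 and 31 probes in the 6 comparisons, in the order of the report), and all of these are among the 1191 probes that the authors' deposited table leaves out, 974 of them tested. Over the 1906 tested probes that the authors' deposited table lists, its fold changes correlated across probes with those computed here by 0.807, 0.885, 0.842, 0.883 and 0.883 for methanol against medium, the 3 doses against methanol and the high against the low dose. The QC self-replicate correlated across probes by 0.992 with HCCPD low replicate 2, whereas the highest pair among the 15 arrays reached 0.780.

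The tests of the vitellogenin pattern below, and the comparison of sizes for HCCPD middle replicate 2, were chosen only after the result was seen.

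Vitellogenin fused with superoxide dismutase was higher by 0.90 ± 0.13 at the high than at the low dose, the probe with the smallest p of that comparison. A constant slide effect cancels by design, as both doses have 1 array on slide 1 and 2 on slide 2, so the differences of 0.85 ± 0.23 and 0.93 ± 0.16 within the slides, the first from 1 array per dose with an SE taken from the spread of all 15 arrays, add no separate test of it. A fault of that probe alone is argued against by the other 2 probes with the same best hit, which differed by 0.44 ± 0.19 on average. A rise of every yolk and egg transcript by as much as 0.90 is argued against by the 3 other members, with a median of 0.052 and a largest SE of 0.24. With that SE the test cannot exclude a smaller general rise, such as the 0.44 of the other 2 probes. Of the 3 members only vitellogenin C1 is a vitellogenin (−0.08 ± 0.24). A response of this yolk gene to dose may remain as a hypothesis, as may a difference in egg or brood stage between samples, which was not tested.

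Arrays of one group lay far apart along one main axis, on which methanol replicates 1 and 2 scored 11.8 and −28.8. Slide is argued against, since methanol replicates 1 and 3 share a slide and scored 11.8 and −12.5, and since scores did not separate the slides (exact permutation p = 0.961, 3432 splits). Exposure group held 35.6% of the variance of the scores (permutation p = 0.358), so most of it lay within groups, where group cannot act; a smaller part set by group stays open. Ribosomal proteins load on one side, and most respiratory, glycolytic and digestive peptidase probes on the other. So do 7 of 8 heat shock and 5 of 6 yolk or egg probes, whereas digestive glycosidases had a median correlation with the axis of only −0.088. A difference in feeding, moult or brood state may lie behind this axis, which was not tested, nor was RNA quality.

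HCCPD middle replicate 2 stood apart in brightness. By the test set beforehand, a raised Cy5 background was met: its negative control spots had a net signal of 13.9 against 4.87 to 8.32 on the other 15 arrays. That bound was too weak, because the control spots rose by 7.47 while the probe median rose by 255, so background as the whole cause is argued against by a size comparison made after seeing these values. The Cy3 channel, which holds the common reference, was brighter as well. Its median was 187, against 131 to 155 on the other 15 arrays. Non-uniform spots numbered 267, against 2 to 33 elsewhere. A response of that sample to the dose would not brighten the reference, which argues against it as the whole cause of the brightness. A smaller part cannot be told apart from a fault of labelling or hybridization. The fold changes of that array from methanol correlated across probes by 0.282 with the mean of the other 2 arrays of the dose. This lay between the bounds of 0.2 and 0.5 set beforehand, whereas those arrays correlated with each other by 0.642. All of these share the methanol mean; taken from medium, its correlations with the 2 arrays were −0.0452 and 0.0954, under the lower bound, against 0.430 between them, which argues against a response shared with the other arrays of the dose and leaves one of that sample alone open.

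Other splits of the same arrays were tested as well. Each comparison of 3 with 3 arrays has 10 splits, so the share with a result as large is never under 0.1. Counting probes at an unadjusted p under 0.05, as many were given by 5 splits for methanol against medium (56; highest other 173), 2 for the low dose (228; 252), 1 for the middle dose (434; 389), 3 for the high dose (166; 330) and 1 for the high against the low dose (275; 223). Counting lists at a preset-correlation p under 0.05, the numbers were 5 (4; highest other 6), 2 (7; 7), 9 (1; 5), 5 (3; 5) and 3 (6; 7). For all HCCPD against all controls, 2 of 100 splits gave as many probes (337; 424), a share under 0.05 in 1 of 12 such counts, with no adjustment for their number. As 1 such share among 12 counts can arise by chance, chance is not excluded for this count. No splits were run for the 173 probes left without medium replicate 1 or the 187 without HCCPD high replicate 2. As many lists were given by 64 of 100 splits (3; 8), so for the lists chance cannot be excluded. Some other splits called more than the real ones, up to 4 probes at the high dose where the real split called 0 in limma. Whether arrays without any structure would give as many was not tested. Splits that followed slide gave 24 probes for the low and 39 for the high dose, fewer than the real splits.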
